A study of Mus musculus with 6 samples.

How the data were processed

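RNA was sequenced from sorted hair germ stem cells of mouse back skin, 6 samples in 3 groups of 2 (WT, LEF1cKO and LEF1_TCF7dKO). Per the labels' protocols, the mice were 60 days old, the cells were taken after depilation and sorted by YFP, integrin b1, CD34, Sca-1 and P-cadherin, and all RNA integrity numbers were above 8. Libraries came from an mRNA kit and were read as pairs on an Illumina HiSeq. All mice carried Sox9-CreER and a YFP reporter; groups were assigned from the sample titles.

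Per the submitters' processing notes, the tools were Bowtie2 2.2.9 and RSEM 1.2.30 with the mm10 build; the annotation release is not given in the sources used here. The expected count values are the authors' RSEM estimates per gene, as deposited, with reads shared between genes split by the model and no normalization. TPM values were made by the authors with RSEM, per the file headers, by scaling for effective length and to the library. FPKM values were made by the authors with RSEM, per the file headers, and were not used in any test. A deposited TPM table of the whole series held the same values as the sample files. Each file listed 46517 genes. Another 92 spike-in identifiers had 0 counts and were dropped. Of the genes, 46005 (98.9%) were matched by Ensembl identifier to GENCODE M21, which gave positions and biotypes. Where 1 of the 114 duplicated symbols was asked for, the identifier with the highest mean count was used.

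Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 with TMM factors (0.962 to 1.04), filterByExpr by group at its defaults, the quasi-likelihood F test and Benjamini-Hochberg adjustment per comparison at 0.05. All 6 libraries were fitted together, which leaves 3 residual degrees of freedom. The biological coefficient of variation was 0.232 and the prior degrees of freedom were 3.11. The comparisons were LEF1cKO against WT, LEF1_TCF7dKO against WT and LEF1_TCF7dKO against LEF1cKO. For genes changed in both knockouts against WT, the overlap was set beside that of independent lists and beside 20 simulated draws of unchanged groups that share the WT libraries. "Rose" and "fell" mean that a gene passed this test.

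The depth per sample ran from 40480615 to 63219925 expected counts. A gene with a count of 0 may hold up to 3 counts by counting error, which is 0.0475 to 0.0741 CPM. These floors cover counting error only, and not the spread between samples. The test was run on simulated data made from 18591 genes of these libraries, with 1.5-fold, 2-fold and 4-fold changes planted. It found 1.56%, 29.5% and 66.2% of them for LEF1cKO against WT, 1.56%, 25.8% and 64.6% for the double knockout against WT, and 2.34%, 35% and 69.2% between the knockouts. Each size of change was planted in 61 to 65 genes against WT and in 123 to 130 between the knockouts. The list test found 1 of 1 planted lists and called 0 of 20 lists with no effect. Genes were drawn independently there, so this does not test the preset correlation used below. In the real libraries the estimated correlation was 0.532 in the cell cycle list and 0.70 in the sebaceous list.

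The tests, the 26 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists held 610 gene symbols, of which 578 were tested. They cover the LEF/TCF family, Wnt targets, Wnt ligands and receptors, bulge, hair germ and matrix, hair shaft and root sheath, BMP, TGF-beta, hedgehog, Notch, FGF and EGF, cell cycle, interfollicular epidermis, isthmus, sebaceous gland, wounded keratinocytes, immediate early genes, interferon, p53, basement membrane and adhesion, fibroblasts, endothelial and mural cells, melanocytes with Schwann and Merkel cells, immune cells, muscle with fat and blood, and the sort and driver genes. Lists were tested with camera of limma 3.58.1 on edgeR logCPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, fry, cameraPR and the members past the threshold over all genes and adjusted over the list alone. Lef1 and Tcf7 were left out of the list tests, and lists with under 5 measured members, which leaves out the LEF/TCF family, were not tested as lists.

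The named genes were Lef1, Tcf7, Tcf7l1 and Tcf7l2, then in each comparison the 8 largest rises and 8 largest falls among genes past the threshold. These had to be separate in every library, to reach 5 TPM in the higher group, and to be neither predicted, pseudogenic nor mitochondrial. In each list, up to 4 members with the smallest p among those past the threshold were named, or the 2 with the highest TPM where none passed, as were the sort genes. Not every gene the rule named is printed, and some genes are not reported here.

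Alternatives were RLE size factors, library size only, no filter, a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma voom, effective length as an offset, limma on log2(TPM + 1) and log2(TPM + 0.1), only the 2 groups compared, the replicate number as a block, each library left out in turn, adjusted p under 0.01, and a 2-fold minimum. Protein-coding genes only and a test without X and Y were added after the data were seen. Copies of genes were found with blastn 2.17.0 in the reference transcripts, at 90% identity or more over 50% of the transcript or more. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The raw reads were not analysed here, so deleted exons and sequence variants were not looked at.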

Results

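Gene expression was compared in hair germ stem cells sorted from the back skin of 60-day-old mice, 3 days after hair depilation had set off a new hair cycle. The 3 groups were wild type (WT), a conditional knockout of Lef1 (LEF1cKO) and the same knockout in Tcf7-null mice (LEF1_TCF7dKO, below the double knockout). Lef1 and Tcf7 encode DNA-binding partners of beta-catenin. Each group held 2 libraries, with totals of 52935313 and 63219925 expected counts in WT, 49656856 and 54282998 in LEF1cKO, and 40480615 and 42987115 in the double knockout. Between 14743 and 16032 genes reached at least 1 TPM per library, and 19640 genes were tested. The labels do not say that the libraries came from separate animals, so p-values here measure only the spread between these samples, which may be technical except between the LEF1cKO libraries, which differ in sex-linked genes (Xist at 0.66 and 380 TPM). Below, effects are log2 fold changes ± SE, levels are mean TPM ± SD, and adjusted p comes from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Where a library was left out, the lone sample of its group was assumed to vary like the other groups.

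The double knockout stood apart from the other groups on the first principal component, and LEF1cKO lay between it and WT there but apart from both on the second. PC1 held 61.8% of the variance, with WT at -74.1 and -90.5, LEF1cKO at -35.4 and 5.74, and the double knockout at 111 and 83.7. PC2 held 16.6%, with WT at 38.9 and 31.2, LEF1cKO at -69.4 and -32.4, and the double knockout at 29.0 and 2.66. Replicates correlated at 0.986 in WT, 0.978 in LEF1cKO and 0.974 in the double knockout, and all pairs of libraries lay between 0.902 and 0.986. No replicate pair was within sampling noise (chi-square per degree of freedom 24.9, 92.9 and 69.1). That noise covers counting error only, so the values do not show whether the libraries came from separate animals. Every library was counted.

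**Figure D1:**
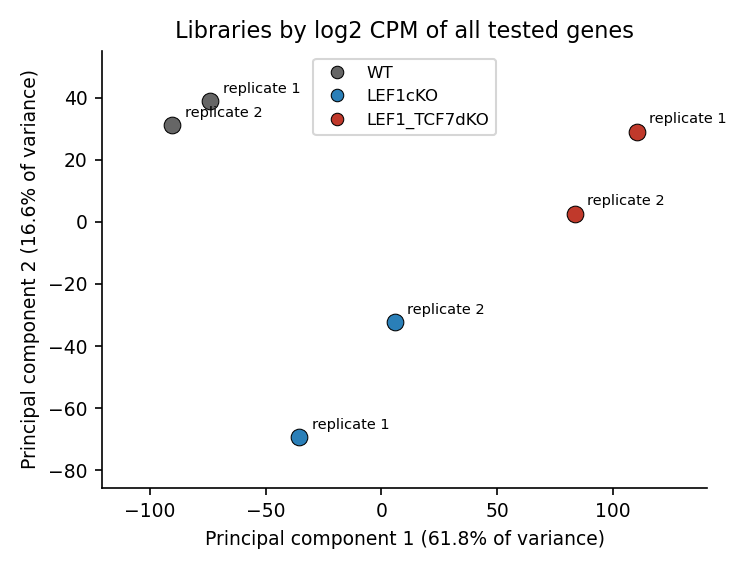
Principal components of the 6 libraries. Each point is a single library.

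Transcripts of both targeted genes were still read in the knockouts. A targeted gene can keep transcript outside the deleted part, so the level does not measure the protein. Lef1 stood at 21.4 and 20.4 TPM in WT, 13.5 and 8.37 in LEF1cKO, and 9.22 and 9.42 in the double knockout. Its change did not pass in LEF1cKO (-0.92 ± 0.25, adjusted p = 0.282; 0.0317 without LEF1cKO replicate 1) and passed in the double knockout (-1.27 ± 0.25, adjusted p = 0.0122). That call was lost without WT replicate 1, WT replicate 2, double knockout replicate 1 or double knockout replicate 2 (highest adjusted p = 0.0827). Tcf7 stood at 26.9 and 36.0 TPM in WT, 29.3 and 27.8 in LEF1cKO, and 13.7 and 18.0 in the double knockout. It fell in the double knockout against WT (-1.37 ± 0.21, adjusted p = 0.00641) and against LEF1cKO (-1.12 ± 0.21, adjusted p = 0.018), and its value in LEF1cKO against WT was -0.25 ± 0.20 (adjusted p = 0.792). The fall against LEF1cKO was lost without LEF1cKO replicate 1 (adjusted p = 0.0741) or double knockout replicate 1 (adjusted p = 0.0962).

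The 2 family members that were not targeted also fell in the double knockout. Tcf7l1, which represses Wnt targets in bulge stem cells, went from 32.9 ± 1.06 TPM in WT to 11.3 ± 0.354 (-1.81 ± 0.18, adjusted p = 0.00331, n = 2 each). Tcf7l2, which encodes another beta-catenin partner, went from 24.1 ± 0.255 to 15.6 ± 0.205 TPM (-0.75 ± 0.11, adjusted p = 0.00633), and that call was lost without WT replicate 2 (adjusted p = 0.0535). In LEF1cKO they stood at 31.3 ± 4.36 and 27.3 ± 2.01 TPM (-0.17 ± 0.17 and 0.11 ± 0.11, adjusted p = 0.84 and 0.861). All 4 members of the family list fell in the double knockout against WT, with as many adjusted over the list alone, and 3, 2, 3 and 3 fell without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2. Against LEF1cKO, 3 fell, and without LEF1cKO replicate 1, LEF1cKO replicate 2 and double knockout replicate 1 the numbers were 2, 4 and 0. In LEF1cKO against WT, 0 passed over all genes and 1 fell adjusted over the list alone; without LEF1cKO replicate 1, 1 fell over all genes.

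**Figure D2:**
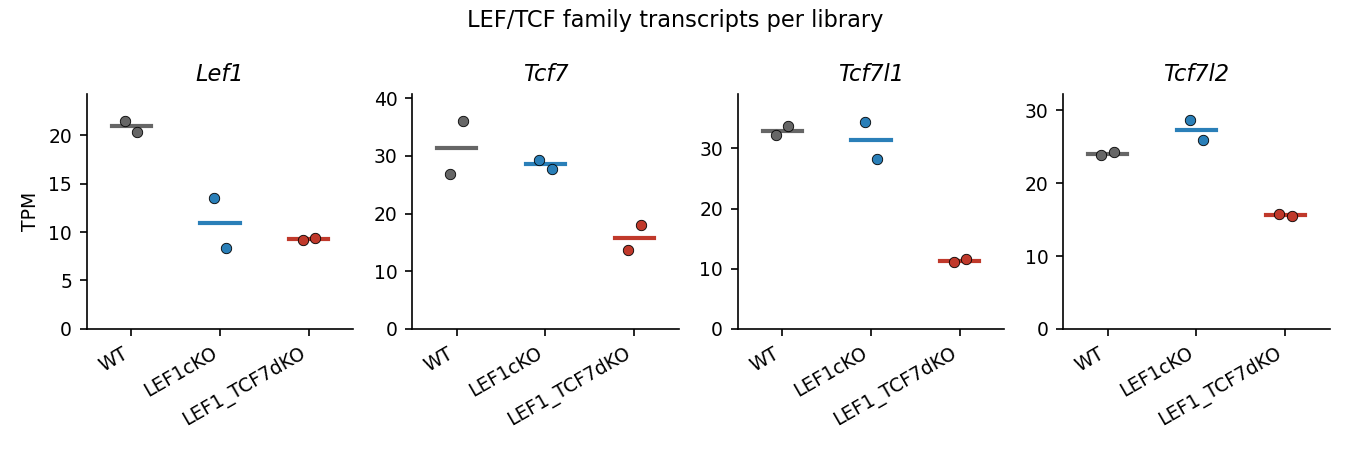
Levels of Lef1, Tcf7, Tcf7l1 and Tcf7l2 in TPM. Points are single libraries and lines are means of 2.

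In LEF1cKO against WT 118 genes passed by edgeR, 422 with no filter and 602 by DESeq2. Rises included keratins and other genes of the differentiated epidermis, a clock repressor and a growth factor binding protein. Among the lists for the hair germ, the cell cycle and Wnt signalling, 0 members passed. A further set of genes was read in WT and far lower in both knockouts, and is taken up below.

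Genes of differentiated keratinocytes were among the rises in LEF1cKO. Krt78 (3.01 ± 0.18, adjusted p = 0.00319; 9.74 ± 1.05 against 1.16 ± 0.205 TPM, n = 2) encodes a keratin of upper epithelial layers and Krt77 (2.67 ± 0.26, adjusted p = 0.0154; 399.9 ± 25.4 against 59.6 ± 21.3 TPM, n = 2) a keratin of the epidermis and sweat duct. Skint7 (3.68 ± 0.43, adjusted p = 0.0264) encodes an immunoglobulin-like protein of epidermal keratinocytes. Krt2, a keratin of the upper spinous layer, rose from 0.205 ± 0.00707 to 4.25 ± 0.757 TPM (4.30 ± 0.52, adjusted p = 0.0308). Igfbp3 (2.74 ± 0.18, adjusted p = 0.00387; 64.2 ± 18 against 8.95 ± 0.58 TPM, n = 2), whose product binds insulin-like growth factors, rose as well. Nr1d1 (3.13 ± 0.21, adjusted p = 0.00387; 50.3 ± 3.56 against 5.47 ± 0.318 TPM, n = 2), which encodes the clock repressor REV-ERB alpha, had a larger rise. Further rises were Gdpd2 (2.58 ± 0.25, adjusted p = 0.0155), a phosphodiesterase gene, and Gsg1l (2.5 ± 0.25, adjusted p = 0.0161), a gene of a glutamate receptor partner. Krt1 and Krt10, keratins of the first suprabasal layer, stood at 764 against 341 TPM and 1467 against 512 TPM but did not pass (1.09 and 1.44, adjusted p = 0.0523 and 0.0515).

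Falls in LEF1cKO included Krt6a (-1.93 ± 0.22, adjusted p = 0.0236; 45.1 ± 14 against 161 ± 6.05 TPM, n = 2), a keratin of the companion layer and of wounded skin. Pttg1 (-1.4 ± 0.12, adjusted p = 0.00945; 25 ± 3.25 against 66.5 ± 3.4 TPM, n = 2), which encodes securin, a regulator of sister chromatid separation, fell too. Dnah7b (-3.27 ± 0.23, adjusted p = 0.00411) encodes a dynein heavy chain, Sqrdl (-3.25 ± 0.36, adjusted p = 0.0223) a mitochondrial sulfide oxidase, Pianp (-2.33 ± 0.24, adjusted p = 0.0173) a membrane protein of neurons, and Hddc3 (-2.0 ± 0.2, adjusted p = 0.0177) a phosphohydrolase. Of the 16 genes named by the rule that passed in LEF1cKO, Nr1d1, Krt78, Igfbp3, Kpna2 and Dnah7b kept their call in every leave-out. Krt77 and Gdpd2 lost it without double knockout replicate 1 or 2 (highest adjusted p = 0.069 and 0.0717). Skint7 and Gsg1l lost it without either WT library or either double knockout library (highest 0.164 and 0.0957). Pttg1 lost it without either WT library (0.1), and Pianp without either WT library or LEF1cKO replicate 1 (0.0949). Sqrdl, Krt2, Hddc3 and Eno1b lost it without either WT library or either LEF1cKO library (highest 0.0936, 0.188, 0.128 and 0.0704). Krt6a lost it without any library but LEF1cKO replicate 2 (0.110).

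In all, 44 genes rose and 74 fell in LEF1cKO against WT, 118 of 19640, and 1882 had an unadjusted p under 0.05. Protein-coding genes made up 39 of the rises and 20 of the falls, and pseudogenes 4 and 46. Without WT replicate 2 the number was 78. The balance of rises and falls depended on the method: 39.2% of the calls were rises with RLE size factors, 26.4% with limma on log2(TPM + 1) and 59% with DESeq2, against 37.3% in the test used here. On simulated data with these depths, 29.5% of planted 2-fold changes and 66.2% of planted 4-fold changes were found, and 18 of 80 calls were false.

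Of the 74 falls, 53 fell by 5 or more on the log2 scale in both knockouts, with at most 17.8 TPM in any knockout library. Pseudogenes made up 41 of them and protein-coding genes 8, and their median level in WT was 29.2 TPM. For 47 a protein-coding relative was found with at least 90% identity over at least 50% of the transcript. One is Gm10184, a copy of Kpna2, whose product carries proteins into the nucleus: Gm10184 was read at 320 TPM in WT, and Kpna2 (2.67 ± 0.14, adjusted p = 0.00207; 298 ± 30.8 against 59.6 ± 3.37 TPM, n = 2) rose as the copy fell. Eno1b (-8.0 ± 0.83, adjusted p = 0.0184; 0.595 ± 0.247 against 145 ± 4.35 TPM, n = 2) is a copy of the glycolysis gene Eno1, and their counts summed changed by 0.01 on the log2 scale. For Kpna2 and Gm10184 the sum changed by -0.36. For the glycolysis gene Gapdh and its copy Gm13394 the sum changed by -0.85 and Gapdh itself by -0.04. Levels of these genes are therefore uncertain, as reads can be placed on either copy.

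**Figure D3:**
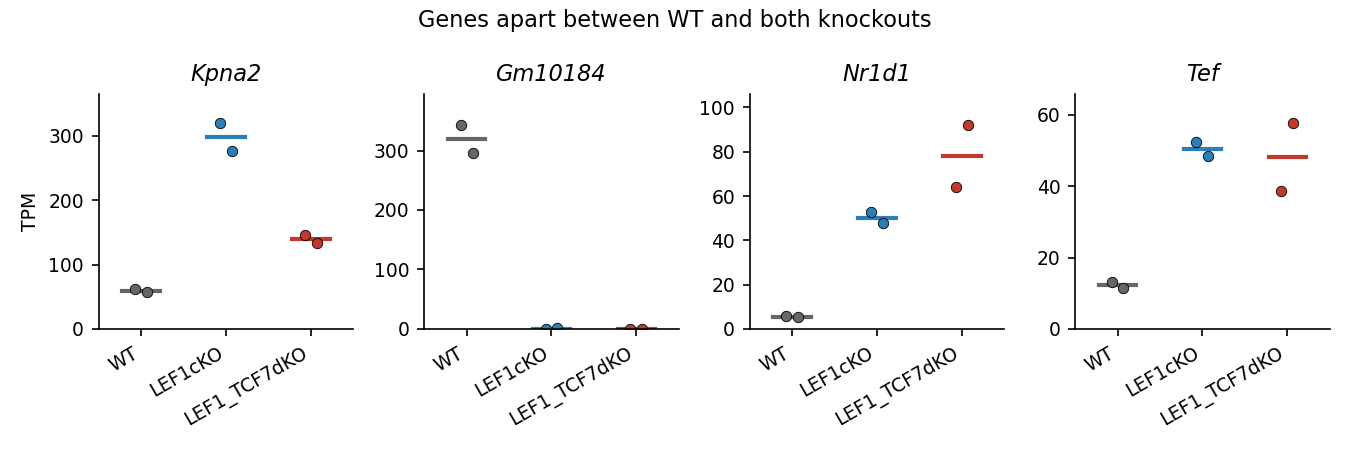
Levels of Kpna2, its copy Gm10184 and the clock genes Nr1d1 and Tef. Points are single libraries and lines are means of 2.

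Tested as lists in LEF1cKO, genes of the epidermis stood higher than other genes, and those of the hair shaft lower. Camera called the interfollicular epidermis list up (adjusted p = 1.49e-05 over lists, median log2 fold change 0.65, adjusted p = 0.914 with an estimated correlation). Of its 27 members 2 rose, Krt77 and Krt2, and 8 adjusted over the list alone; each of the 6 leave-outs left 1. Immune cell markers were called up too (adjusted p = 1.49e-05, median 1.22, adjusted p = 0.914 with an estimated correlation), with 0 of 28 members past the threshold, 11 rises adjusted over the list alone, and 4 rises without WT replicate 1. Fibroblast and dermal papilla markers (adjusted p = 0.00651, median 0.68) and the basement membrane list (adjusted p = 0.033, median 0.16) were called up. Both had adjusted p = 0.914 with an estimated correlation, with 0 of 24 and 0 of 30 members past. The lists called down were hair shaft genes (adjusted p = 0.00118, median -0.80), cell cycle genes (adjusted p = 0.00232, median -0.13) and melanocyte, Schwann and Merkel cell markers (adjusted p = 0.00232, median -0.68). Each had adjusted p = 0.914 with an estimated correlation, and 0 of 23, 40 and 17 members passed. Among them, Krt28 of the inner root sheath had a value of -0.80 ± 0.53 (adjusted p = 0.738; 0.0289 without LEF1cKO replicate 1), Top2a of replicating cells -0.25 ± 0.22, and Dct of melanocytes -0.71 ± 0.34.

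The epidermis and immune calls held in every leave-out, and the other list calls in LEF1cKO did not. The hair shaft call was lost without LEF1cKO replicate 2 (adjusted p = 0.0691), as was the cell cycle call (0.984). The fibroblast call was lost without WT replicate 2 (0.405) or LEF1cKO replicate 2 (0.197), and the melanocyte call without WT replicate 1 (0.109) or LEF1cKO replicate 2 (0.197). The basement membrane call was lost without WT replicate 1 (0.109), WT replicate 2 (0.0902) or LEF1cKO replicate 1 (0.261). The rotation test fry, which asks whether a list's genes on balance move one way, called 0 lists in LEF1cKO (smallest adjusted p = 0.230, 2 with an unadjusted p under 0.05), against 7 by camera. None of the camera calls in any comparison held with an estimated correlation.

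Wnt genes and hair germ genes did not pass in LEF1cKO. Over all genes, 0 of 20 Wnt target and feedback genes, 0 of 36 Wnt ligands, receptors and inhibitors, 0 of 24 bulge genes and 0 of 26 hair germ and matrix genes passed by edgeR, and adjusted over the list alone 0, 0, 1 and 2 did. Their camera adjusted p was 0.805, 0.805, 0.354 and 0.330. Ccnd1, a cyclin gene, stood at 141 ± 14.6 against 118 ± 1.18 TPM and Lhx2, a stem cell transcription factor, at 385 ± 24.2 against 359 ± 31.3 TPM (0.17 ± 0.17 and 0.02 ± 0.26). For the BMP, TGF-beta, hedgehog, Notch and FGF lists, 0 members passed over all genes and 2, 1, 2, 0 and 0 adjusted over the list alone (camera adjusted p = 0.451, 0.770, 0.805, 0.770 and 0.704). Of the lists for isthmus, sebaceous, immediate early, interferon, p53, endothelial and muscle genes and the genes used in the sort, 0 members passed over all genes. Camera gave adjusted p = 0.315, 0.805, 0.8, 0.451, 0.517, 0.702, 0.189 and 0.949, and adjusted over the list alone 2 isthmus and 4 immediate early genes passed and 0 in the rest. The wounded keratinocyte list (adjusted p = 0.805) held 1 fall of 29, Krt6a, with 2 rises and 2 falls adjusted over the list alone; the fall stayed only without LEF1cKO replicate 2.

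Leaving out 1 library changed some of these results. Without LEF1cKO replicate 1, camera called the hair germ list (adjusted p = 0.0152), the interferon list (5.22e-06) and the sebaceous list (0.0207). Without LEF1cKO replicate 2 it called the TGF-beta list (0.030), the isthmus list (0.00424), the sebaceous list (0.00424) and the interferon list (0.00728), the last 2 in the opposite direction. The muscle list was called without double knockout replicate 1 (0.00693) or 2 (0.00846). Without LEF1cKO replicate 1, 1 Wnt target, 1 hair shaft, 2 BMP and 2 immediate early genes fell and 1 Wnt ligand and 1 bulge gene rose. Without LEF1cKO replicate 2, 1 hedgehog and 1 isthmus gene fell and 1 bulge and 1 immediate early gene rose. The sebaceous list had a median of 0.11 and a mean of 0.24 though camera pointed down. The sort genes (-0.07 and 0.12) and Wnt ligands (-0.02 and 0.14) had medians below 0 and means above it, and camera pointed up.

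A large part of the transcriptome differed between the double knockout and WT. All 40 cell cycle genes fell, and 13 of 23 hair shaft and root sheath genes fell. Genes of the differentiated epidermis rose strongly. Markers of fibroblasts, vessels and immune cells rose beside them. Wnt targets, Wnt ligands and bulge genes moved in both directions.

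In the double knockout against WT, 3540 genes rose and 3849 fell, 7389 of 19640 (37.6%), and 9529 had an unadjusted p under 0.05. Protein-coding genes made up 3273 of the rises and 3446 of the falls, and 43.9% of the 15317 tested passed. A list with a share near that is not set apart by its count. Changes of at least 2-fold were 2498 rises and 1326 falls. Without WT replicate 1 the number of changed genes was 2671, without WT replicate 2 it was 1968, and without double knockout replicate 1 it was 2994. On simulated data 25.8% of planted 2-fold changes were found, and 11 of 70 calls were false. The simulation changed far fewer genes than were called here, and the adjustment depends on that share. Its rates therefore do not carry over to the 7389 calls. Every gene named below for this comparison kept its call in all 6 leave-outs unless a loss is given.

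Cell cycle genes fell as a block in the double knockout. All 40 members fell, with as many adjusted over the list alone. Cenpa (-1.24 ± 0.09, adjusted p = 0.00172; 86.2 ± 4.09 against 197 ± 5.69 TPM, n = 2) encodes the centromere histone and Birc5 (-1.48 ± 0.11, adjusted p = 0.00207; 57.4 ± 3.61 against 158 ± 4.67 TPM, n = 2) the survivin of the chromosomal passenger complex. Ccnb2 (-1.44 ± 0.12, adjusted p = 0.00229; 51.3 ± 2.84 against 126 ± 4.47 TPM, n = 2) encodes a mitotic cyclin and Aurka (-1.55 ± 0.13, adjusted p = 0.00251; 24.9 ± 0.24 against 66.3 ± 1.8 TPM, n = 2) a spindle kinase. The median was -1.32. Camera called the list down (adjusted p = 3.97e-16, adjusted p = 0.611 with an estimated correlation), and fry gave adjusted p = 0.0218.

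More hair germ, matrix and hair shaft genes fell than rose. Of 26 hair germ and matrix genes, 11 fell and 5 rose, with as many adjusted over the list alone. Dlx3 (-4.34 ± 0.38, adjusted p = 0.00265; 6.07 ± 0.771 against 112 ± 14.9 TPM, n = 2), a homeobox gene of the hair matrix, and Msx1 (-5.2 ± 0.65, adjusted p = 0.0044; 1.14 ± 0.0424 against 38.2 ± 10.4 TPM, n = 2), a homeobox gene of matrix progenitors, fell. Shh (-1.28 ± 0.15, adjusted p = 0.00408; 5.94 ± 0.0707 against 13.1 ± 0.919 TPM, n = 2), the gene of the ligand sent out by the hair germ, fell too. Foxn1 (1.79 ± 0.23, adjusted p = 0.00446; 5.34 ± 0.417 against 1.41 ± 0.148 TPM, n = 2), a gene that drives keratinocyte differentiation, rose. The hair germ list as a whole was not called (camera adjusted p = 0.272, median -0.27). Without WT replicate 2 the falls numbered 6 and without double knockout replicate 1 they numbered 7, and the rises were 2, 2, 3 and 3 without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2. Of 23 hair shaft and root sheath genes, 13 fell (15 adjusted over the list alone) and 3 rose, with 1 rise without WT replicate 2. Krt28 (-5.42 ± 0.65, adjusted p = 0.00408; 4.12 ± 0.728 against 161 ± 20.2 TPM, n = 2) and Krt73 (-4.7 ± 0.58, adjusted p = 0.00421) encode inner root sheath keratins and Krt75 (-5.08 ± 0.61, adjusted p = 0.00408) a companion layer keratin. Dsc1 (2.27 ± 0.25, adjusted p = 0.00371; 58.7 ± 23.2 against 11 ± 0.368 TPM, n = 2), a desmosomal cadherin gene of the epidermis, rose. Krt25, another root sheath keratin, fell from 17.8 to 0.07 TPM, and its call was lost without double knockout replicate 1 (adjusted p = 0.0548). Camera called the hair shaft list down (adjusted p = 0.00104, median -3.07, adjusted p = 0.611 with an estimated correlation), which a stricter filter of 10 CPM ended, and fry gave adjusted p = 0.0379.

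Epidermal differentiation genes rose. Of 27 interfollicular epidermis genes, 22 rose and 0 fell, with as many adjusted over the list alone. Krt1 (3.04 ± 0.16, adjusted p = 0.00108; 3089 ± 131 against 341 ± 37.4 TPM, n = 2) and Krt10 (3.39 ± 0.22, adjusted p = 0.00142; 5902 ± 20.5 against 512 ± 106 TPM, n = 2) encode the keratin pair of the spinous layer, and Krt77 (4.67 ± 0.28, adjusted p = 0.00133; 1666 against 59.6 TPM) a further epidermal keratin. Dmkn (2.0 ± 0.12, adjusted p = 0.00133; 1087 against 344 TPM) encodes a secreted protein of upper layers. Camera called the list up (adjusted p = 1.33e-10, median 2.0, adjusted p = 0.611 with an estimated correlation), and fry gave adjusted p = 0.0176. Large rises outside the lists were Skint7 (5.65 ± 0.46, adjusted p = 0.00229) and Skint5 (5.38 ± 0.32, adjusted p = 0.0013), sister genes of epidermal keratinocytes, Pyy (7.04 ± 1.05, adjusted p = 0.00614), a gut peptide gene, and Mmrn1 (5.73 ± 0.83, adjusted p = 0.00578), a gene of lymphatic vessels. Flg, the filaggrin gene, is listed under several gene identifiers, so its level is uncertain; 1 of them stood at 0 in both WT libraries and at 6.58 ± 3.9 TPM in the double knockout. Large falls were Foxe1 (-6.96 ± 0.96, adjusted p = 0.00519), a forkhead gene of the hair follicle, and Hsd11b2 (-6.06 ± 0.59, adjusted p = 0.00331), whose product inactivates glucocorticoids. The histone gene Hist1h2ai, which has near-identical copies, stood at 0 in the double knockout and at 9.37 ± 1.15 TPM in WT.

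**Figure D4:**
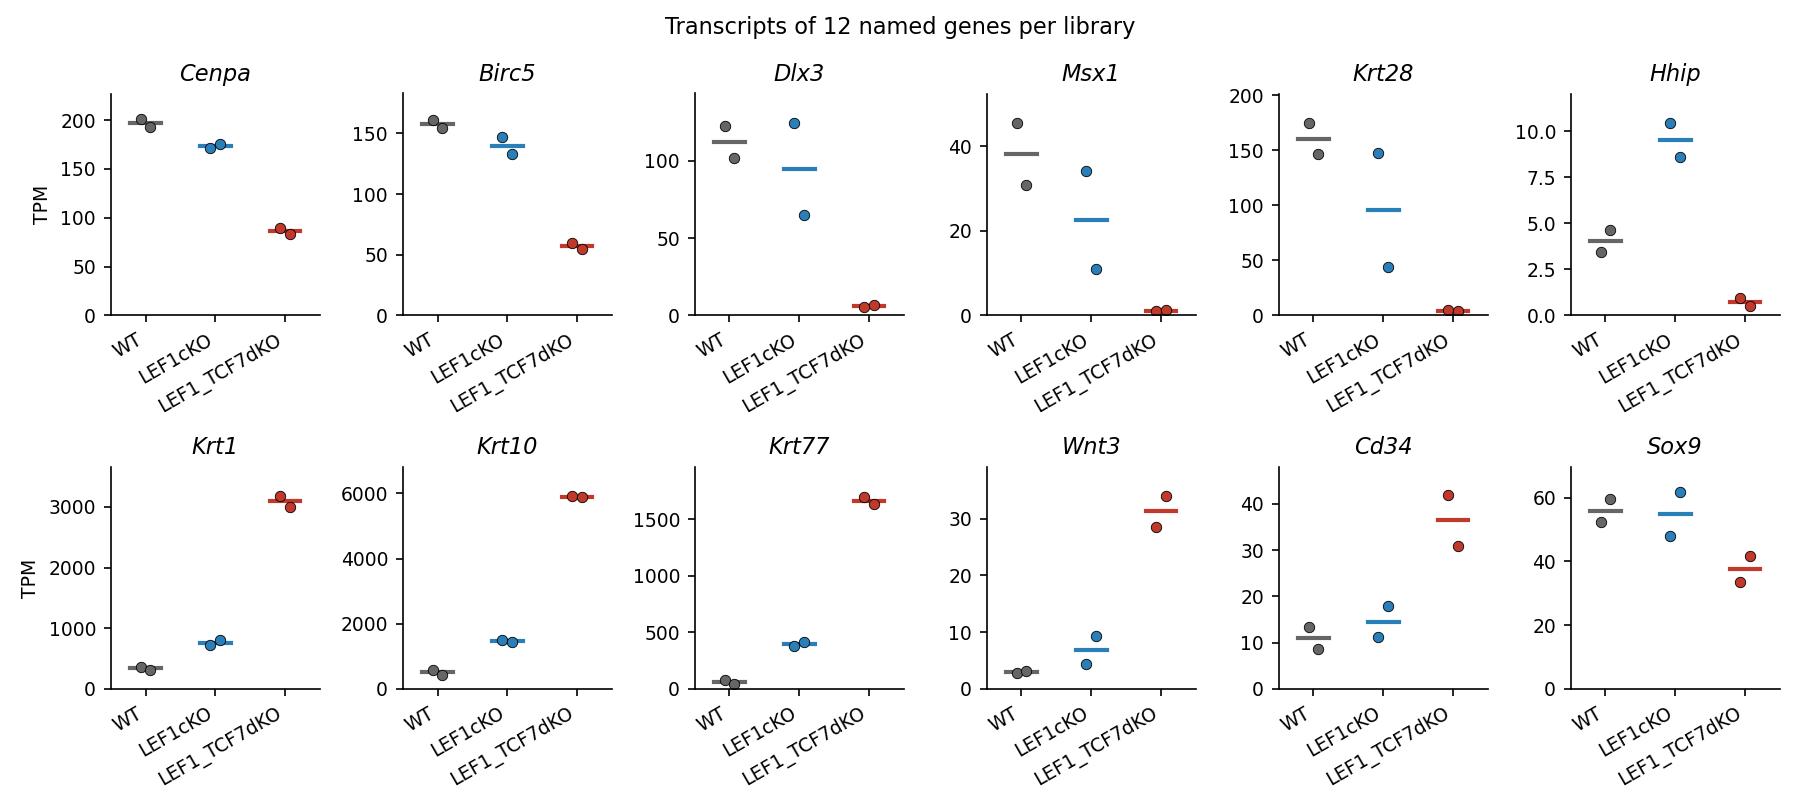
Levels of 12 genes of the cell cycle, hair lineage, epidermis, Wnt signalling and bulge in TPM. Points are single libraries and lines are means of 2.

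Genes of the upper follicle, of the sebaceous gland and of wounded skin rose more often than they fell. Of 15 isthmus and infundibulum genes 6 rose and 0 fell, with as many adjusted over the list alone (camera adjusted p = 0.0138, median 1.19), for example Aqp3 (1.52 ± 0.14, adjusted p = 0.00271; 297 ± 10.2 against 91.6 ± 5.52 TPM, n = 2), a water and glycerol channel gene. Of 29 sebaceous gland genes 8 rose (12 adjusted over the list alone) and 3 fell (camera adjusted p = 0.0209, median 1.55). Dgat2 (2.58 ± 0.23, adjusted p = 0.00271; 49.8 ± 10.7 against 7.57 ± 0.94 TPM, n = 2) encodes an enzyme of triglyceride synthesis and Elovl7 (1.43 ± 0.22, adjusted p = 0.00646) a fatty acid elongase, while the desaturase genes Fads1 (-1.12 ± 0.09, adjusted p = 0.00228) and Fads2 (-1.78 ± 0.25, adjusted p = 0.00553) fell. Of 29 genes of activated and wounded keratinocytes 11 rose and 3 fell, with as many adjusted over the list alone (camera adjusted p = 0.00885, median 1.35). Il1rn (2.55 ± 0.14, adjusted p = 0.00108; 35.7 ± 4.82 against 4.77 ± 0.622 TPM, n = 2) and Il1b (3.36 ± 0.45, adjusted p = 0.0049; 42 ± 2.03 against 3.44 ± 1.93 TPM, n = 2) encode the interleukin-1 receptor antagonist and interleukin-1 beta. Hbegf (1.77 ± 0.11, adjusted p = 0.00133; 55.8 against 14.8 TPM) encodes a growth factor of migrating keratinocytes, and Mmp9 (3.56 ± 0.38, adjusted p = 0.00354) a matrix protease. The 3 lists were called up, with adjusted p = 0.611, 0.697 and 0.611 with an estimated correlation; fry did not call the sebaceous list (0.357), and the 10 CPM filter ended the wound call. The isthmus and wound calls were lost without double knockout replicate 2 (adjusted p = 0.0617 and 0.102), and the sebaceous call without double knockout replicate 1 (0.233). Isthmus rises numbered 3, 1, 2 and 3 without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2, and 11 and 10 without LEF1cKO replicate 1 and replicate 2, where 1 isthmus gene fell in each. Sebaceous rises were 2 without WT replicate 1, WT replicate 2 or double knockout replicate 1, 17 without either LEF1cKO library, and falls 2 without either WT library. Wound rises were 4 without WT replicate 2 and 7 without double knockout replicate 2; falls were 1 without WT replicate 1, WT replicate 2 or double knockout replicate 1.

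Wnt genes moved both ways. Of 20 Wnt target and feedback genes 8 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.375, median 0.40). Notum (1.91 ± 0.31, adjusted p = 0.00739; 9.52 ± 0.566 against 2.65 ± 0.467 TPM, n = 2), which encodes a secreted Wnt deacylase, rose, and Ccnd1 (-1.0 ± 0.17, adjusted p = 0.00833; 64.3 ± 14.5 against 118 ± 1.18 TPM, n = 2), a cyclin gene, fell; the Ccnd1 call was lost without WT replicate 2 (adjusted p = 0.0603). Of 36 Wnt ligands, receptors and secreted inhibitors 12 rose and 11 fell (13 and 12 adjusted over the list alone; camera adjusted p = 0.970). Wnt3 (3.28 ± 0.34, adjusted p = 0.0034; 31.3 ± 3.81 against 2.92 ± 0.233 TPM, n = 2), a canonical ligand gene, Lrp4 (1.58 ± 0.18, adjusted p = 0.00393; 65.8 against 20.6 TPM), a receptor gene, and Dkk2 (4.2 ± 0.51, adjusted p = 0.00417), an inhibitor gene, rose. Sfrp1 (-2.26 ± 0.21, adjusted p = 0.00286; 19.1 ± 3.48 against 83.2 ± 11.9 TPM, n = 2), which encodes a secreted inhibitor, fell. Of 24 bulge genes 8 rose and 7 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.985). Col17a1 (1.66 ± 0.21, adjusted p = 0.00455; 789 ± 77.8 against 223 ± 5.68 TPM, n = 2), a hemidesmosome collagen gene of stem cells, and Ccdc3 (2.29 ± 0.35, adjusted p = 0.00646; 44.3 against 8.23 TPM) rose, and Nfib (-0.98 ± 0.14, adjusted p = 0.00531; 72.7 against 136 TPM), a nuclear factor gene of follicle stem cells, fell beside Tcf7l1. For Wnt ligands the median was -0.06 and the mean 0.36, with camera pointing up, and for bulge genes 0.01 and 0.10, with camera pointing down. Without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2, Wnt target rises numbered 3, 2, 2 and 3 and falls 3, 1, 2 and 3. Wnt ligand rises in that order were 6, 5, 7 and 10 and falls 6, 7, 3 and 8, and bulge rises were 3, 2, 3 and 5 and falls 4, 3, 5 and 8.

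Hedgehog, BMP and TGF-beta genes fell more often than they rose, and camera called only the hedgehog list. Of 17 hedgehog genes 8 fell (9 adjusted over the list alone) and 1 rose, for example Hhip (-2.84 ± 0.26, adjusted p = 0.00271; 0.72 ± 0.311 against 4.05 ± 0.841 TPM, n = 2), a target that binds the ligand, and Smo (-1.08 ± 0.14, adjusted p = 0.0047; 68.3 ± 10.4 against 132 ± 4.73 TPM, n = 2), the signal transducer. Camera called the hedgehog list down (adjusted p = 0.0325, median -0.38, adjusted p = 0.611 with an estimated correlation). That call was lost with the 10 CPM filter, on log2(TPM + 1), and without LEF1cKO replicate 1 (adjusted p = 0.110), LEF1cKO replicate 2 (0.107) or double knockout replicate 1 (0.0766). Of 27 BMP genes 10 fell and 5 rose (11 and 6 adjusted over the list alone; camera adjusted p = 0.311, called by fry). Id4 (-2.55 ± 0.25, adjusted p = 0.00331; 11 ± 0.262 against 58.5 ± 9.58 TPM, n = 2), a BMP target, and Smad6 (-1.22 ± 0.14, adjusted p = 0.00396), a feedback inhibitor, fell, and Bmp2 (1.91 ± 0.26, adjusted p = 0.00513; 15.7 ± 0.346 against 3.81 ± 0.672 TPM, n = 2), a ligand gene, rose. Of 23 TGF-beta genes 9 fell and 5 rose, with as many adjusted over the list alone (camera adjusted p = 0.195). Col4a1 (-1.5 ± 0.13, adjusted p = 0.00271; 81.7 ± 0.184 against 208 ± 7.76 TPM, n = 2), a basement membrane collagen gene, and Itgb6 (-2.03 ± 0.28, adjusted p = 0.00516), an activator of TGF-beta, fell, and Tgfbi (1.68 ± 0.2, adjusted p = 0.00408; 233 against 66 TPM) and Tgfbr2 (1.0 ± 0.13, adjusted p = 0.00469; 43 against 19.5 TPM) rose. Without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2, hedgehog falls numbered 5, 3, 4 and 9 and rises 0, 0, 1 and 0, and rises were 3 without either LEF1cKO library. BMP falls in that order were 6, 6, 5 and 9 and rises 3, 1, 2 and 3, and TGF-beta falls were 4, 2, 6 and 6 and rises 3, 2, 3 and 4.

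Among Notch, growth factor, stress and interferon genes, rises outnumbered falls. Camera called only the interferon list, and over all 15317 tested protein-coding genes 3273 rose and 3446 fell (43.9%). Of 20 Notch genes 6 rose and 2 fell, with as many adjusted over the list alone (camera adjusted p = 0.334), among them Notch2 (1.27 ± 0.17, adjusted p = 0.00472; 22 ± 3.92 against 8.32 ± 0.728 TPM, n = 2), a receptor gene, and Dtx1 (2.93 ± 0.42, adjusted p = 0.00572), a target gene. Of 24 FGF, EGF and MAPK feedback genes 8 rose and 5 fell, with as many adjusted over the list alone (camera adjusted p = 0.290). Dusp5 (0.98 ± 0.1, adjusted p = 0.00334; 33.2 against 15.3 TPM) encodes a phosphatase of ERK, Tgfa (1.68 ± 0.24, adjusted p = 0.00556; 11.5 against 3.35 TPM) an EGF receptor ligand and Fgf7 (3.3 ± 0.51, adjusted p = 0.00664) a ligand from dermal cells. Of 30 immediate early genes 11 rose (13 adjusted over the list alone) and 3 fell (camera adjusted p = 0.0891, called without WT replicate 2 at 0.0381, without double knockout replicate 1 at 0.0142, and with the 10 CPM filter). Klf4 (1.21 ± 0.14, adjusted p = 0.00376; 510.4 against 200.1 TPM) and Klf2 (1.6 ± 0.19, adjusted p = 0.00408), which encode zinc-finger factors, rose, and the heat shock genes Hsp90aa1 (-1.86 ± 0.19, adjusted p = 0.00337; 268 against 932 TPM) and Hspa1b (-1.8 ± 0.24, adjusted p = 0.00475; 427 against 1348 TPM) fell. Of 25 p53 and cell death genes 7 rose (8 adjusted over the list alone) and 3 fell (camera adjusted p = 0.295). Cdkn1a (1.42 ± 0.11, adjusted p = 0.00229; 262 ± 33 against 88 ± 3.95 TPM, n = 2), the p21 inhibitor of the cell cycle, rose. Of 34 interferon genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), for example Oas2 (4.07 ± 0.69, adjusted p = 0.00807; 2.05 against 0.14 TPM), an antiviral gene. Camera called the list up (adjusted p = 0.000446, median 1.08, adjusted p = 0.611 with an estimated correlation), and fry did not (0.12). Fry called the Notch, FGF and p53 lists.

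The counts of these lists moved when 1 library was left out. In the order WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2, Notch rises numbered 2, 2, 2 and 6, FGF rises 5, 4, 5 and 8, immediate early rises 3, 4, 8 and 4, p53 rises 1, 1, 3 and 3, and interferon rises 2, 1, 2 and 3. Falls in that order were 0, 0, 1 and 1 for Notch, 0, 0, 1 and 1 for FGF, 1, 1, 2 and 3 for p53, and 0, 0, 0 and 1 for interferon. Without either LEF1cKO library, interferon rises numbered 21, and immediate early falls 5. For genes of these lists named here (Notch2, Dtx1, Dusp5, Tgfa, Klf4, Cdkn1a and Oas2) no call was lost.

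Basement membrane genes moved both ways. Of 30 genes of the basement membrane, integrins and cadherins 13 rose and 7 fell (15 and 9 adjusted over the list alone; camera adjusted p = 0.290, called by fry). The collagen IV genes Col4a1 and Col4a2 (-1.15 ± 0.15, adjusted p = 0.0045; 51.6 ± 1.02 against 104 ± 6.29 TPM, n = 2) fell while Col17a1 rose. Without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2 the rises numbered 4, 2, 6 and 12 and the falls 4, 3, 4 and 5.

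Markers of fibroblasts, vessels and immune cells rose in the double knockout beside the epidermal genes. Of 24 fibroblast and dermal papilla markers 16 rose and 1 fell (17 and 1 adjusted over the list alone). Col1a1 (3.65 ± 0.59, adjusted p = 0.00731; 396 ± 49.1 against 29.1 ± 19.7 TPM, n = 2) and Col1a2 (3.59 ± 0.54, adjusted p = 0.00633; 416 ± 59.1 against 31.3 ± 19.4 TPM, n = 2) encode type I collagen and Vim (1.65 ± 0.26, adjusted p = 0.00699; 492 against 145 TPM) vimentin. Of 20 endothelial and mural markers 16 rose (17 adjusted over the list alone), for example Des (3.78 ± 0.48, adjusted p = 0.00445; 15.4 ± 6.19 against 1.01 ± 0.382 TPM, n = 2) and Myh11 (4.4 ± 0.63, adjusted p = 0.00562; 29.3 ± 17.8 against 1.25 ± 0.686 TPM, n = 2) of smooth muscle. Of 28 immune markers 18 rose, with as many adjusted over the list alone, for example H2-Eb1 (3.47 ± 0.38, adjusted p = 0.00357; 186 ± 4.33 against 15.3 ± 7.03 TPM, n = 2) for antigen presentation. Cd68 (2.45 ± 0.19, adjusted p = 0.00227; 26.8 ± 3.91 against 5.03 ± 0.764 TPM, n = 2) and Itgam (3.67 ± 0.36, adjusted p = 0.00331) mark myeloid cells and Cd207 (2.88 ± 0.32, adjusted p = 0.00365) Langerhans cells. The 3 lists were called up by camera (adjusted p = 0.000439, 0.000201 and 3.22e-05, medians 2.09, 2.84 and 2.92), each with adjusted p = 0.611 with an estimated correlation. Fry called the immune list (adjusted p = 0.0444) but not the fibroblast (0.079) or endothelial list (0.0712). Of 17 melanocyte, Schwann and Merkel cell markers 5 rose, with as many adjusted over the list alone (camera adjusted p = 0.744), for example Mbp (2.88 ± 0.29, adjusted p = 0.0034; 37.3 ± 13.5 against 4.01 ± 0.693 TPM, n = 2), a myelin gene. Of 15 muscle, adipose and red blood cell markers 2 rose and 4 fell, with as many adjusted over the list alone (camera adjusted p = 0.744).

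In the order WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2, fibroblast marker rises numbered 15, 7, 3 and 13 and falls 0, 0, 0 and 1. Endothelial rises were 4, 3, 8 and 17, melanocyte list rises 2, 2, 3 and 4, and muscle list rises 0, 0, 0 and 7 with falls 1, 1, 3 and 2. Immune rises stayed between 14 and 18. From 0 falls, 1 melanocyte list gene fell without either LEF1cKO library, and 1 endothelial and 1 immune marker without double knockout replicate 2. The melanocyte list had a median of -0.26, a mean of 0.20 and camera pointing up, and the muscle list 2.01, 1.16 and camera pointing down.

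The genes behind the sort and the Cre driver changed too, though the sort itself selects on their proteins. Cd34 (1.54 ± 0.28, adjusted p = 0.00954, 36.4 ± 7.81 against 11.1 ± 3.35 TPM, n = 2), a surface marker gene, and Ly6a (2.22 ± 0.41, adjusted p = 0.00968, 104 ± 9.76 against 20.6 ± 8.36 TPM, n = 2), the Sca-1 gene, rose. Cdh3 (-0.93 ± 0.18, adjusted p = 0.0109; 75.9 ± 14.1 against 132 ± 2.7 TPM, n = 2), the P-cadherin gene of the hair germ, and Sox9 (-0.71 ± 0.16, adjusted p = 0.0198; 37.6 ± 5.81 against 56 ± 5.11 TPM, n = 2), the driver gene, fell. Itgb1, the integrin beta 1 gene, did not pass (-0.33 ± 0.11, adjusted p = 0.0632; 0.0371 and 0.0291 without LEF1cKO replicate 1 and replicate 2). The Cd34 and Ly6a calls were lost without WT replicate 2 or double knockout replicate 1 (highest adjusted p = 0.0588 and 0.0561), and the Cdh3 and Sox9 calls without WT replicate 1, WT replicate 2 or double knockout replicate 1 (highest 0.0658 and 0.138). So 2 of 5 rose and 2 fell, 2 and 3 adjusted over the list alone. Rises numbered 2, 0, 0 and 2 and falls 0, 0, 0 and 2 without WT replicate 1, WT replicate 2, double knockout replicate 1 and double knockout replicate 2, and 3 fell without either LEF1cKO library. The list was not called (camera adjusted p = 0.828, median -0.33, mean 0.36).

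**Figure D5:**
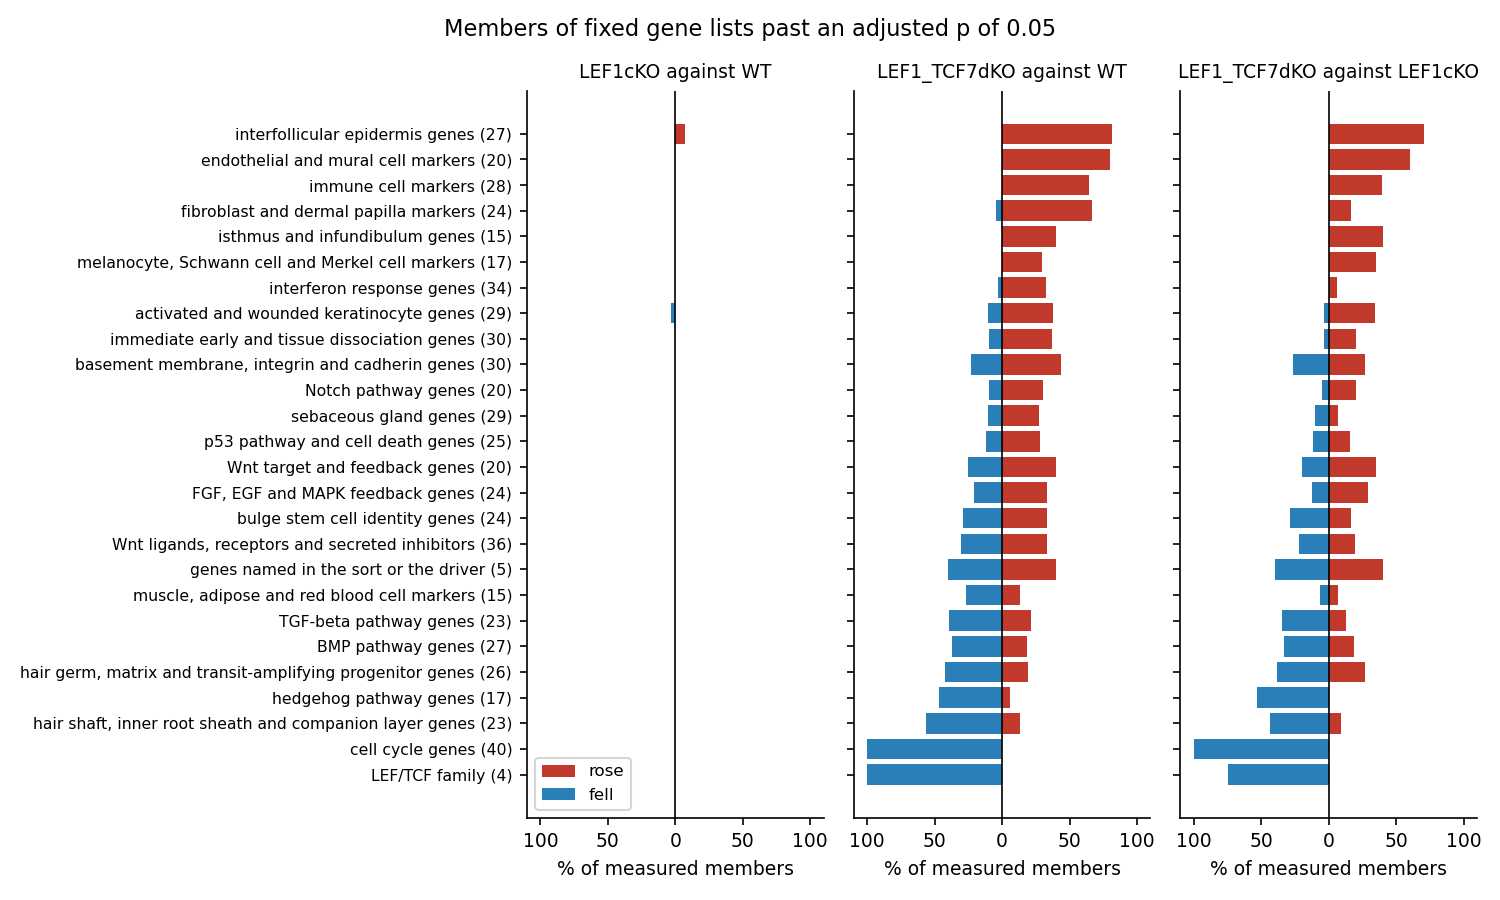
Percent of measured members of each gene list that rose or fell in the 3 comparisons.

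The double knockout also differed from LEF1cKO, where the same Lef1 deletion is present with Tcf7 intact. By camera the cell cycle, hedgehog and hair shaft lists were lower and the epidermis list higher, though no list call held with an estimated correlation. Nearly all calls of single genes were lost when double knockout replicate 1 was left out, and why was not tested. Camera still called 12 of its 14 lists in that leave-out, but it takes genes as nearly separate, so this decides nothing.

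Against LEF1cKO, 2192 genes rose and 2760 fell in the double knockout, 4952 of 19640 (25.2%), and 8147 had an unadjusted p under 0.05. Protein-coding genes made up 2064 of the rises and 2586 of the falls, and 30.4% of the 15317 tested passed. The number was 2201 without WT replicate 1, 2124 without WT replicate 2, 1652 without LEF1cKO replicate 1, 2884 without double knockout replicate 2 and 1 without double knockout replicate 1, where 5884 had an unadjusted p under 0.05. On simulated data 35.0% of planted 2-fold changes were found and 13 of 149 calls were false. Far fewer genes were changed in that simulation than were called here, so these rates do not carry over to the 4952 calls. All 105 genes named by the rule that passed here lost their call without double knockout replicate 1, those below at adjusted p = 0.0777 or more. Other losses are given in the text.

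The cell cycle and epidermis lists had the most calls. All 40 cell cycle genes fell, with as many adjusted over the list alone, and Cenpa (-0.98 ± 0.09, adjusted p = 0.0107; 86.2 ± 4.09 against 173 ± 3.05 TPM, n = 2) and Birc5 (-1.22 ± 0.11, adjusted p = 0.0107; 57.4 ± 3.61 against 139.8 ± 9.68 TPM, n = 2) are examples. Camera called the list down (adjusted p = 2.87e-18, median -1.21, adjusted p = 0.607 with an estimated correlation). Of 27 epidermis genes 19 rose (22 adjusted over the list alone, with 1 fall). Krtdap (1.94 ± 0.12, adjusted p = 0.0107; 1646 ± 233 against 386 ± 52.8 TPM, n = 2), a gene of differentiating keratinocytes, Krt1 (1.95 ± 0.16, adjusted p = 0.0107; 3089 ± 131 against 764 ± 60.4 TPM, n = 2) and Sbsn (1.6 ± 0.15, adjusted p = 0.0107), which encodes suprabasin, are examples. Camera called the list up (adjusted p = 1.65e-09, median 1.58, adjusted p = 0.607 with an estimated correlation). Fry called these lists alone (adjusted p = 0.0314 for both). Without double knockout replicate 1, 0 members of either list passed.

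More hair lineage, hedgehog, BMP and TGF-beta genes fell than rose. Of 26 hair germ and matrix genes 10 fell and 7 rose (11 and 7 adjusted over the list alone; camera adjusted p = 0.215). Dlx3 (-4.04 ± 0.37, adjusted p = 0.0107; 6.07 ± 0.771 against 94.5 ± 42.2 TPM, n = 2), Dlx2 (-4.34 ± 0.57, adjusted p = 0.0113) and Cux1 (-2.63 ± 0.35, adjusted p = 0.0113; 67.7 ± 0.375 against 353 ± 164 TPM, n = 2), transcription factor genes of the hair matrix and sheath, fell. Of 23 hair shaft genes 10 fell and 2 rose (13 and 2 adjusted over the list alone), for example Krt28 (-4.63 ± 0.63, adjusted p = 0.0115); camera called the list down (adjusted p = 0.00639, median -1.81, adjusted p = 0.607 with an estimated correlation). Of 17 hedgehog genes 9 fell (10 adjusted over the list alone) and 0 rose. Among them were Hhip (-3.95 ± 0.27, adjusted p = 0.0107; 0.72 ± 0.311 against 9.52 ± 1.33 TPM, n = 2), Gli3 (-0.97 ± 0.13, adjusted p = 0.0116) and Ptch1 (-1.7 ± 0.27, adjusted p = 0.0138; 64.4 ± 22.3 against 200.4 ± 9.81 TPM, n = 2), the receptor gene. The Ptch1 call was also lost without LEF1cKO replicate 1 (adjusted p = 0.0532). Camera called the hedgehog list down (adjusted p = 0.0173, median -0.60) and the TGF-beta list down (adjusted p = 0.0398, median -0.46), both with adjusted p = 0.607 with an estimated correlation. Of 23 TGF-beta genes 8 fell and 3 rose (8 and 4 adjusted over the list alone), for example Col4a1 (-1.25 ± 0.13, adjusted p = 0.0107) and Smad3 (-0.88 ± 0.1, adjusted p = 0.0108). Of 27 BMP genes 9 fell and 5 rose (10 and 6 adjusted over the list alone; camera adjusted p = 0.399), for example Id4 (-1.94 ± 0.25, adjusted p = 0.0111) and Bmp2 (1.93 ± 0.26, adjusted p = 0.0114). Large falls outside the lists were Hsd11b2 (-5.75 ± 0.59, adjusted p = 0.0107), Foxe1 (-5.74 ± 0.93, adjusted p = 0.0141) and Cps1 (-4.34 ± 0.33, adjusted p = 0.0107), a urea cycle gene. The hair shaft, hedgehog and TGF-beta calls ended with the 10 CPM filter, the TGF-beta call also on log2(TPM + 1).

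Leave-outs moved these lists, and without double knockout replicate 1 each held 0 calls. Hair germ falls were 6 without either WT library, and rises 3, 3, 2 and 3 without WT replicate 1, WT replicate 2, LEF1cKO replicate 1 and double knockout replicate 2. Hair shaft falls were 5 without double knockout replicate 2, and rises 1 without LEF1cKO replicate 1. Hedgehog falls were 5 without either WT library and 4 without LEF1cKO replicate 1, and 2 hedgehog genes rose without LEF1cKO replicate 2, where the list call was lost (adjusted p = 0.155). BMP falls were 5 without either WT library or double knockout replicate 2 and 4 without LEF1cKO replicate 1, with rises 3, 3, 2 and 1. TGF-beta falls were 5 without either WT library, LEF1cKO replicate 1 or double knockout replicate 2, and 13 without LEF1cKO replicate 2; rises were 1 without LEF1cKO replicate 1. The TGF-beta call was lost without LEF1cKO replicate 1 (0.178), double knockout replicate 1 (0.085) or double knockout replicate 2 (0.0563).

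Wnt and bulge genes moved both ways against LEF1cKO. Of 20 Wnt targets 7 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.440). Axin2 (0.73 ± 0.12, adjusted p = 0.0139; 40 ± 1.79 against 24.4 ± 4.14 TPM, n = 2), a feedback target, rose, and Ccnd1 (-1.17 ± 0.17, adjusted p = 0.0123; 64.3 against 141 TPM) and Lgr5 (-1.29 ± 0.25, adjusted p = 0.0208), a stem cell receptor gene, fell. The Axin2 and Lgr5 calls were also lost without LEF1cKO replicate 1 (adjusted p = 0.0571 and 0.0846). Of 36 Wnt ligands, receptors and inhibitors 7 rose and 8 fell (11 and 11 adjusted over the list alone; camera adjusted p = 0.981), for example Wnt3 (2.14 ± 0.32, adjusted p = 0.0124; 31.3 ± 3.81 against 6.87 ± 3.44 TPM, n = 2) and Sfrp1 (-1.62 ± 0.2, adjusted p = 0.0111; 19.1 ± 3.48 against 56.6 ± 13.1 TPM, n = 2). Of 24 bulge genes 4 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.477), for example Nfib (-1.03 ± 0.14, adjusted p = 0.0113). For Wnt ligands the median was 0.00 and the mean 0.22, with camera pointing up. Wnt target rises numbered 3, 3, 0 and 2 without WT replicate 1, WT replicate 2, LEF1cKO replicate 1 and double knockout replicate 2, and falls were 2 without LEF1cKO replicate 1 and 7 without LEF1cKO replicate 2. Ligand rises were 1 and 2 and falls 4 and 5 without LEF1cKO replicate 1 and double knockout replicate 2. Bulge rises were 2, 2, 1, 7 and 1 without WT replicate 1, WT replicate 2, LEF1cKO replicate 1, LEF1cKO replicate 2 and double knockout replicate 2, and falls 2 without LEF1cKO replicate 1. Without double knockout replicate 1 all of these counts were 0.

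Upper follicle, wound and immediate early genes rose more often than they fell against LEF1cKO. Of 15 isthmus genes 6 rose (8 adjusted over the list alone), for example Aqp3 (1.58 ± 0.14, adjusted p = 0.0107). Of 29 sebaceous genes 2 rose and 3 fell, with as many adjusted over the list alone, for example Dgat2 (1.57 ± 0.22, adjusted p = 0.0119) and Fads1 (-0.96 ± 0.09, adjusted p = 0.0107). Of 29 wound genes 10 rose and 1 fell, with as many adjusted over the list alone. Krt6a (1.49 ± 0.21, adjusted p = 0.0121; 131 ± 21.5 against 45.1 ± 14 TPM, n = 2), which fell in LEF1cKO against WT, rose here, as did Il1rn (1.75 ± 0.13, adjusted p = 0.0107; 35.7 ± 4.82 against 9.18 ± 0.41 TPM, n = 2). Camera called these 3 lists up (adjusted p = 0.00119, 0.00669 and 0.000462), with adjusted p = 0.607, 0.635 and 0.607 with an estimated correlation. Of 30 immediate early genes 6 rose and 1 fell (11 and 2 adjusted over the list alone), for example Klf4 (1.05 ± 0.14, adjusted p = 0.0113). Of 34 interferon genes 2 rose, Mx2 and Ifit3, with 0 adjusted over the list alone. Camera called both lists up (adjusted p = 0.00725 and 0.000448), each with adjusted p = 0.607 with an estimated correlation. Of 20 Notch genes 4 rose and 1 fell and of 24 FGF genes 7 rose and 3 fell, with as many adjusted over the list alone (camera adjusted p = 0.403 and 0.215), for example Dusp5 (0.75 ± 0.1, adjusted p = 0.0113) and Hbegf (1.31 ± 0.11, adjusted p = 0.0107). Of 25 p53 genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.477), for example Cdkn1a (1.06 ± 0.11, adjusted p = 0.0107). Of 30 basement membrane genes 8 rose and 8 fell (15 and 9 adjusted over the list alone; camera adjusted p = 0.734), for example Hspg2 (-1.08 ± 0.14, adjusted p = 0.0111), the perlecan gene.

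These counts moved as well, all to 0 without double knockout replicate 1. Isthmus rises were 3 without either WT library or double knockout replicate 2. Sebaceous rises were 18 without LEF1cKO replicate 2 and falls 1 without either WT library or double knockout replicate 2, and the list call was lost without LEF1cKO replicate 1 (adjusted p = 0.0717) or double knockout replicate 1 (0.168). Wound rises were 5, 6 and 6 without WT replicate 2, LEF1cKO replicate 1 and double knockout replicate 2, and falls 0 and 2 without LEF1cKO replicate 1 and replicate 2. Immediate early rises were 2 without double knockout replicate 2 and falls 3 without LEF1cKO replicate 2, and the call was lost without either (0.0958 and 0.175). Interferon rises were 0 without WT replicate 1, WT replicate 2 or LEF1cKO replicate 1, 19 without LEF1cKO replicate 2 and 1 without double knockout replicate 2, and Mx2 lost its call without any library, Ifit3 without any but LEF1cKO replicate 2 (highest adjusted p = 0.132 and 0.169). Notch rises were 2, 1 and 2 without WT replicate 1, WT replicate 2 and LEF1cKO replicate 1, and falls 3 without LEF1cKO replicate 2 and 0 without any other library. FGF falls were 0 without either WT library, LEF1cKO replicate 1 or double knockout replicate 2, and camera called the list without LEF1cKO replicate 1 (0.0405). In the order WT replicate 1, WT replicate 2, LEF1cKO replicate 1, LEF1cKO replicate 2 and double knockout replicate 2, p53 rises were 2, 2, 2, 6 and 1 and falls 1, 1, 0, 5 and 3, and basement membrane rises 2, 2, 1, 8 and 4 and falls 7, 7, 5, 8 and 8.

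Markers of other cell types also rose against LEF1cKO. Of 20 endothelial and mural markers 12 rose (17 adjusted over the list alone). Myh11 (4.36 ± 0.63, adjusted p = 0.0121; 29.3 ± 17.8 against 1.37 ± 0.651 TPM, n = 2), Acta2 (3.85 ± 0.56, adjusted p = 0.0121; 83.5 ± 44.5 against 5.51 ± 0.417 TPM, n = 2) and Des (3.77 ± 0.48, adjusted p = 0.0111) are genes of smooth muscle. The Acta2 call was also lost without LEF1cKO replicate 1 (adjusted p = 0.0546). Of 28 immune markers 11 rose (13 adjusted over the list alone), for example Cd68 (1.35 ± 0.19, adjusted p = 0.0116), and of 24 fibroblast markers 4 (2 adjusted over the list alone). Of 17 melanocyte, Schwann and Merkel cell markers 6 rose, with as many adjusted over the list alone. Sox10 (1.47 ± 0.17, adjusted p = 0.0108; 11.3 ± 0.375 against 3.9 ± 0.219 TPM, n = 2), a neural crest factor gene, and Mbp (2.14 ± 0.29, adjusted p = 0.0113) are examples. Camera called the 4 lists up (adjusted p = 9.79e-05, 0.000247, 0.00311 and 0.0177), each with adjusted p = 0.607 with an estimated correlation. Of 15 muscle markers 1 rose and 1 fell, Ckm and Myh1 (6 and 4 adjusted over the list alone; camera adjusted p = 0.964). The Ckm call was also lost without LEF1cKO replicate 1 (adjusted p = 0.0796), and the Myh1 call without either WT library, LEF1cKO replicate 1 or double knockout replicate 2 (highest 0.0975). Among the 5 sort genes Cd34 and Ly6a rose and Cdh3 and Sox9 fell (1.24, 1.58, -0.79 and -0.60, adjusted p = 0.0273, 0.0361, 0.0276 and 0.0447), with as many adjusted over the list alone (camera adjusted p = 0.799). Their calls were also lost without LEF1cKO replicate 1, those of Cd34 and Ly6a without double knockout replicate 2, those of Cdh3 and Sox9 without either WT library, and that of Sox9 without LEF1cKO replicate 2 (highest 0.135, 0.148, 0.12 and 0.19). The sort list had a median of -0.26 and a mean of 0.23, with camera pointing down.

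In the order WT replicate 1, WT replicate 2, LEF1cKO replicate 1, LEF1cKO replicate 2 and double knockout replicate 2, endothelial rises numbered 5, 4, 3, 7 and 16, immune rises 15, 15, 1, 7 and 1, fibroblast rises 7, 7, 0, 7 and 2 and melanocyte list rises 4, 4, 3, 5 and 5. Muscle rises were 1, 1, 0, 1 and 7 and falls 0, 0, 0, 1 and 0, and sort gene rises 2, 2, 0, 2 and 0 and falls 0, 0, 0, 1 and 2. Without double knockout replicate 2, 1 fibroblast and 1 endothelial marker fell, and without double knockout replicate 1 all of these counts were 0. The melanocyte call was lost without LEF1cKO replicate 2 (adjusted p = 0.396) or double knockout replicate 2 (0.112).

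Most genes that changed in LEF1cKO changed the same way in the double knockout. Of the 118 genes, 116 were also called against WT in the double knockout with the same sign, 43 higher and 73 lower, and 53 of those lower are the genes described above that fell by 5 or more in both knockouts, most of them pseudogenes. Of the 59 protein-coding genes 57 were called in both with the same sign. Of the 118, 37 lay further from WT in the double knockout than in LEF1cKO and 12 lay closer, by the direct comparison. Of those higher in LEF1cKO 31 lay further and 4 closer, and of those lower 6 and 8. These counts depend on single libraries. Without WT replicate 1, WT replicate 2, LEF1cKO replicate 1, LEF1cKO replicate 2, double knockout replicate 1 and double knockout replicate 2, 36, 12, 55, 23, 0 and 13 lay further and 5, 8, 8, 43, 0 and 11 closer. Without WT replicate 2 the shared genes were 75. Krt77, for example, stood at 59.6, 399.9 and 1666 TPM in WT, LEF1cKO and the double knockout. Both comparisons use the same 2 WT libraries, and WT could not be split. With no effect, simulated sharing of the WT libraries gave 0.15 such genes on average, and independent lists would give 22.4. The simulation changed no gene in either knockout, whereas 7389 genes passed in the double knockout. These numbers and the simulated values below therefore cannot show sharing beyond what the common WT libraries would give. The log2 fold changes correlated at 0.733 (0.490 simulated), with a covariance of 0.847 against 0.0568, and 70.4% of genes had the same sign (66.7% simulated). In protein-coding genes the correlation was 0.651 and the covariance 0.376.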

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

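Only protein-coding genes alone and the test without X and Y were chosen after the results were seen. For LEF1cKO against WT (118 genes) the count was 422 with no filter, 602 with DESeq2, 31 with protein-coding genes only, 45 at adjusted p under 0.01, and 78 to 138 with a library left out. For the double knockout against WT (7389) it was 3022 at adjusted p under 0.01, 3824 with a 2-fold minimum, and 1968 to 8333 with a library left out. Against LEF1cKO (4952) it was 2418 on log2(TPM + 1) with no filter, 2585 with only the 2 groups compared, 2227 with a 2-fold minimum, and 1 to 5973 with a library left out. At adjusted p under 0.01 it was 0 by edgeR (smallest 0.0107; 8147 with an unadjusted p under 0.05) and 4354 by DESeq2. The count shared by both knockouts (116) was 389 with no filter, 527 with DESeq2, 29 with protein-coding genes only, 45 at adjusted p under 0.01, and 75 to 135 with a library left out. A stricter threshold lowers a count by construction; for the other settings the cause was not tested. Without X and Y the counts were 120, 7133, 4790 and 117. With the replicate number as a block they were 80, 6435, 3635 and 78, though deviations of equal numbers correlated only at -0.04, 0.06 and -0.03. Lists called (7, 11 and 14) were 0, 0 and 0 with an estimated correlation, 0, 12 and 2 with fry, and 5 to 9, 9 to 12 and 11 to 14 with a library left out. In LEF1cKO the sebaceous list changed direction between leave-outs (adjusted p = 0.00424 to 0.996), as did the interferon list (5.22e-06 to 0.765), and the cause was not tested. As a log2 ratio of TPM, Lef1 changed by -1.17 in the double knockout against WT and Tcf7 by -0.99 against WT and -0.85 against LEF1cKO. No named gene reversed. Of 16 named calls in LEF1cKO, 4 were lost with the replicate block, 4 with only the 2 groups, 6 on log2(TPM + 0.1), 7 on log2(TPM + 1) with no filter and up to 9 with a library left out. Of 110 in the double knockout up to 8 were lost by method and 29 with a library left out, and of 105 against LEF1cKO up to 29 and all 105. Depth leaves genes under 0.0475 to 0.0741 CPM unread.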

Other observations

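All tests of explanations below were chosen after the results were seen, each with its prediction written first except those for another genetic background of the WT mice, for a single library on all list members, the count of follicle genes and the clock without Nr1d1, written after their values were seen; the rule for shared copies was made stricter after its values were seen. The sex-linked genes did not have 1 pattern in all libraries. Xist, the transcript that silences an X chromosome, stood at 0.66 TPM in LEF1cKO replicate 1 and between 309 and 380 TPM in the others. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 38.8, 65.6, 13.1 and 15.6 TPM in that library. In the others Ddx3y was at most 0.1 TPM. The labels give the sex of every sample as mixed.

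Evening clock genes stood higher in both knockouts than in WT. Of 10 clock genes grouped as the evening arm, chosen after Nr1d1 was seen, 3 rose in LEF1cKO and 9 in the double knockout. Peak times were not measured here. Nr1d1 stood at 5.7 and 5.25 TPM in WT, 52.8 and 47.7 in LEF1cKO, and 64 and 92.3 in the double knockout. Nr1d2, its sister gene, rose in LEF1cKO (1.66 ± 0.19, adjusted p = 0.0245, edgeR), as did Tef, a clock output factor (1.95 ± 0.23, adjusted p = 0.0286; 50.4 ± 2.93 against 12.3 ± 1.2 TPM, n = 2 each). Per1 did not pass in either. Of 5 morning genes 0 fell in either knockout, and Npas2 and Clock rose in the double knockout (2.51 and 0.5).

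The first pattern is the 53 genes read in WT and far lower in both knockouts. Reads moving between copies cannot be told apart from a real loss: the summed level of copies and closest relative changed by a median of -0.12 in LEF1cKO, and a full loss of the copies would give -0.24, too close to part them; of the 15 families where a loss would pass -0.25, 11 lay nearer no change and 4 nearer a loss, and 24 of 34 relatives were higher. In the double knockout the sum changed by -0.448, which cannot be told apart from a real fall either, because the relatives themselves differ by -0.377 between the knockouts. Another read length or annotation for WT was excluded (0.0043 percentage points between libraries), as was DNA of another strain linked to Lef1 (1.89% of the genes within 20 Mb). The genes lie on 18 chromosomes, so another genetic background of the WT mice cannot be told apart from genotype without base-level data, which were not analysed here; the hypothesis is that a strain difference in copies, rather than the loss of Lef1, may set these genes apart.

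In the second pattern, markers of other skin cell types rose in the double knockout. A lower share of follicle cells that raises all other types alike predicts that the lists agree. The melanocyte, Schwann and Merkel list (17 genes) lay -3.18 from the immune list (28 genes) in median log2 fold change (permutation p = 0.00091, 100000 permutations). The permutation counts genes as separate, though the estimated correlation was 0.597 in the immune list and 0.286 in the melanocyte list. It therefore cannot exclude that explanation. The fibroblast, endothelial and immune lists had medians of 2.09, 2.84 and 2.92, against -0.26 in the melanocyte list. A single library as the whole source was argued against by the medians of all 89 members of the 4 lists, called or not. They were 1.48 without replicate 1 (95% bootstrap interval 0.97 to 1.95) and 2.69 without replicate 2, against 2.37 with both. The bootstrap drew genes as separate, so its interval covers the spread between genes and not between libraries. Of the 55 called markers 47 (85.5%) were over 2-fold above WT in each double knockout library, which decides nothing as both libraries chose them, and only 28 kept their call without replicate 1 (fibroblast rises 16 to 3, endothelial 16 to 8) while the median change of all 55 went from 2.97 to 2.56 and their median SE from 0.529 to 0.515; why calls ended was not tested. With dilution by epidermal cells as the whole cause of falling genes, follicle genes should fall no further than Sox9. Of all 48 hair germ and hair shaft genes, 19 lay over 2 of their own SE below the bound set by Sox9 (-1.04). The hair germ list as a whole had a median of -0.27 (-2.6 in its 11 falling genes), and 16 of the 48 were above 0. These values argue against that dilution only if Sox9 tracks follicle RNA in every genotype, which was not tested. A hypothesis is that more immune, vessel and dermal cells, or their RNA, came through the sort in the double knockout. Such cells would have had to pass its selection on YFP and the surface markers. Counts of sorted cells could settle that hypothesis, and genotype stays an untested biological cause.

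The third pattern is the clock. Another time of day at collection cannot be told apart from genotype: in LEF1cKO evening genes lay 1.76 above morning genes in median log2 fold change (exact permutation p = 0.005, 3003 arrangements; 1.75 and p = 0.015 without Nr1d1, the gene that led to the list), with a morning median of -0.09. The prediction asked for the same in both knockouts, and in the double knockout the difference was 1.28 (exact permutation p = 0.0753) with a morning median of 0.391, which keeps it open. A shift of all genes alike was argued against, as the evening median lay at percentile 100 of 10000 expression-matched lists in both knockouts. A shift of related genes alone was not tested. The hypothesis is that the knockouts may have been collected at another hour than WT; the labels give no hour, and genotype stays open as a biological cause that was not tested.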
